A study of Homo sapiens with 20 samples.

How the data were processed

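Gene expression was measured by RNA sequencing in primary human umbilical vein endothelial cells (HUVECs), the cells that line the vein of the umbilical cord, bought from ATCC. Per the labels' protocols, the cells were cultured for 24 h with recombinant human CYR61 protein at 0.05, 0.5 or 5 µg/ml, or without it. CYR61, whose gene is now named CCN1, is a secreted protein of the extracellular matrix that binds integrins and heparan sulfate proteoglycans. Each of the 4 groups holds 5 libraries, 20 in all, and groups were taken from the labels. The labels do not say whether the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. The labels describe no group that received the buffer of the protein or an inactive protein.

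Per the labels' protocols, 10 ng of total RNA per library was made into full-length cDNA with the SMARTer Ultra Low kit, sheared, ligated to adapters, amplified and sequenced as paired reads of 150 bases. The kit does not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. No molecular identifiers are described in the labels, so PCR copies of a molecule may be counted more than once. Per the submitters' processing notes, DRAGEN was used. Its version, the genome build, the annotation release and the counting settings are not given in the sources used here, and no coordinates are printed for that reason.

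The count table deposited by the authors holds an estimated count per Ensembl gene and library, not normalized. It has 60871 lines, of which 200 repeated a gene ID and were removed, leaving 60671 genes. Of its values, 12.0% were not whole numbers, and all were rounded to whole numbers before testing. For each dose the authors also deposited a comparison with the control, with log2 fold changes and log2 expression levels per the file headers. The same tables hold p-values and adjusted p-values that the authors deposited, and the model behind them is not given in the sources used here. Values from those tables are printed only where they are named as the authors' deposited tables.

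Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 16026 genes holding 99.9% of all counts, and libraries were scaled with TMM factors. One quasi-likelihood model with a mean per group was fitted to all 20 libraries, so that all comparisons share 1 estimate of the spread. Each dose was compared with control, 5 with 0.5 µg/ml, and 0.5 with 0.05 µg/ml. A joint test of the 3 doses asked for a change at any dose, and a linear trend over the 4 groups in order gave a slope per dose step. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Levels are counts of a gene per 1000000 counts of the library (CPM) after TMM scaling, given as mean ± SD with n = 5 libraries per group. Fold changes are edgeR estimates on the log2 scale with their standard errors (SE). The mean biological coefficient of variation was 9.73%. Totals ran from 22289924 to 35022362 counts per library, so counting error weighs most in genes of a few CPM, such as CXCL6, and differences in genes below that level were often not detectable. SDs and standard errors hold the spread between libraries as well as counting error.

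In all, 38 gene lists with 813 genes were fixed for pathways, states of endothelium and other cell types, and all 813 genes were found in the count table. Of the lists, 35 had at least 5 tested members and were tested with camera in limma 3.58.1 on voom log2 CPM, with the preset correlation between genes of 0.01. The adjusted p is over the 35 lists of a comparison. Each list was also tested with a correlation estimated from the data and with fry, which asks whether the members of a list move in 1 direction on balance. The 3 lists with fewer tested members have gene counts only. Genes in more than 1 list numbered 42. A list mean is the mean limma-voom log2 fold change of its tested members. For single members, the edgeR p was adjusted over all genes tested and, separately, over the list alone.

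The genes named are given by a rule. It takes the CCN family, and for 5 µg/ml against control the 10 largest rises, the 10 largest falls and the 5 smallest p among genes that passed, at a mean of at least 1 CPM. The other comparisons take 5, 5 and 3 in the same way, and where fewer than 3 genes passed, the 3 smallest p as values only. It further takes the 4 list members with the smallest p at 5 µg/ml, and any list member that passed over all genes tested. Genes of chromosome Y, XIST and genes without a symbol were left out of naming. Values of 1 gene are not reported here. List members named outside the rule are marked as chosen after their values were seen. Transcripts of CXCL1 and CXCL3, of the metallothionein genes and of the ribosomal protein genes resemble close paralogs or pseudogenes, and BCYRN1 has many genomic copies. Their values are uncertain because the way shared reads were divided is not given in the sources used here.

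The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. These alternatives were other scaling factors, no filter or a stricter filter on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, and models of only the libraries compared. Others were a stricter threshold, a floor on the fold change, each library left out in turn, and for lists the estimated correlation and fry. Chosen after the data were examined were the tests of lists between doses, the removal of a trend with gene length and GC content, and the removal of 3 libraries at 0.05 µg/ml. Length and GC content came from the longest GENCODE v29 transcript of each gene, matched by Ensembl ID for 98.7% of the tested genes and 707 of 708 tested list members.

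Library properties were compared with exact two-sided permutation tests, whose smallest possible p with 5 against 5 libraries is 0.00794. Comparisons with the same control libraries share the chance values of those libraries, so 100 sets of unchanged groups were simulated against shared controls. Each comparison was also refitted with its libraries split in other ways, 100 splits with the real one included. The tests were checked on simulated counts for 5 µg/ml against control with 16026 genes and 50 genes changed at each of 4 fold sizes. edgeR recovered 32% of genes changed 1.25-fold, 74% of those changed 1.5-fold, 84% at 2-fold and 98% at 4-fold, with 6 false calls among 150. With 200 genes changed at once, the adjusted threshold is easier to pass than where few genes change, so recovery in the data may be lower. In all simulations genes were drawn independently of each other. Counts of same-group libraries differed by more than sampling noise in every pair, with a chi-square per gene of at least 3.33, so no library was counted as a copy of another.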

Results

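To assess how endothelial cells respond to CYR61, a matrix protein that binds integrins, transcript levels were measured in HUVECs after 24 h with 0, 0.05, 0.5 or 5 µg/ml of the recombinant protein. Each group had 5 libraries. Total counts per library ran from 22289924 to 35022362 with a median of 26116997. The mean total was 27351921 ± 2816719 in control, 24977542 ± 1418887 at 0.05, 28763322 ± 4097682 at 0.5 and 26522535 ± 3640899 at 5 µg/ml (SD, n = 5). In all, 16026 genes were tested.

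The libraries at 0.05 µg/ml were not alike. On the first principal component, which held 11.1% of the variance, replicates 1, 2 and 3 at 0.05 µg/ml lay at 27.2, 22.2 and 31.7, and replicates 4 and 5 at -18.0 and -7.75. All 5 libraries at 5 µg/ml lay between -19.4 and -11.2, the controls between -13.3 and 15.5, and those at 0.5 µg/ml between -5.98 and 7.25. Transcripts of ribosomal proteins took 7.68% ± 0.14 of the counts in control, 8.10% ± 0.35 at 0.05, 7.86% ± 0.12 at 0.5 and 7.56% ± 0.31 at 5 µg/ml (SD, n = 5). The difference at 0.05 µg/ml had an exact permutation p = 0.00794, the smallest that 5 against 5 libraries can give, and an adjusted p = 0.119 over 15 tests of library properties. None of the 15 passed.

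**Figure D1:**
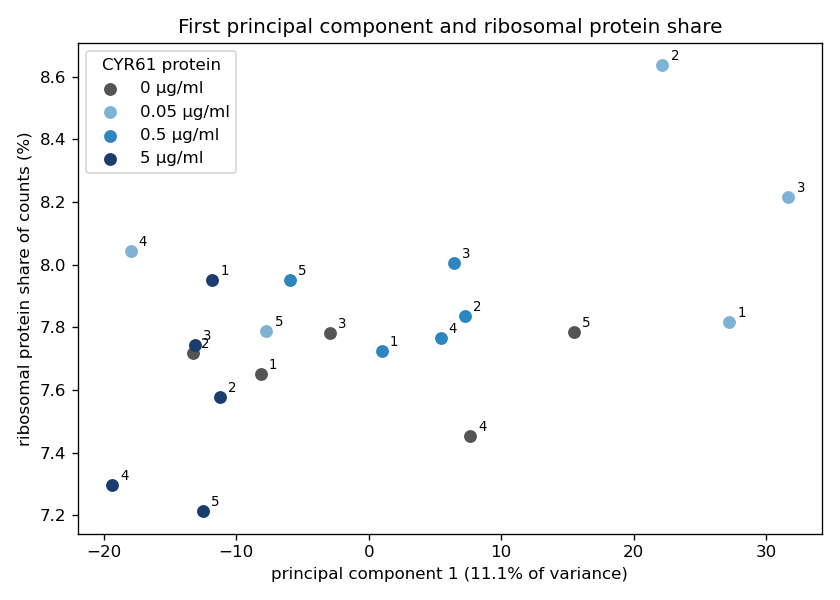
Each point is 1 of the 20 libraries, coloured by dose and numbered by replicate, with the first principal component of log2 CPM on the x axis (11.1% of variance) and the share of counts in ribosomal protein genes in percent on the y axis. Replicates 1, 2 and 3 at 0.05 µg/ml lie at 27.2, 22.2 and 31.7 on the x axis, to the right of all other libraries.

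CCN1 (ENSG00000142871), the gene that encodes the added protein, was at 100 ± 7.49 CPM in control, 104 ± 6.93 at 0.05, 106 ± 4.05 at 0.5 and 109 ± 6.20 at 5 µg/ml. Its log2 fold changes against control were 0.047 (SE 0.055), 0.086 (SE 0.055) and 0.13 (SE 0.055), and none passed over all genes tested (adjusted p = 0.563 at 5 µg/ml). CCN2 (ENSG00000118523), the related connective tissue growth factor, was at 446 ± 37.0 CPM in control and 481 ± 18.5 at 5 µg/ml (log2 fold change 0.11, SE 0.046, adjusted p = 0.563). Of the 6 genes of the CCN family, these 2 were expressed highly enough to test. Both passed at 5 µg/ml when adjusted over the list alone (adjusted p = 0.0289 for each), and neither did at the lower doses.

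At 5 µg/ml, the highest dose, transcripts of secreted inflammatory proteins and of the transferrin receptor rose against control. CXCL1 (ENSG00000163739), a chemokine that attracts neutrophils, rose from 135 ± 3.39 to 203 ± 3.48 CPM (log2 fold change 0.58, SE 0.056, n = 5 per group, edgeR adjusted p = 2.81e-06). CCL2 (ENSG00000108691), which attracts monocytes, rose 1.85-fold from 11.8 ± 1.42 to 21.9 ± 3.66 CPM (log2 fold change 0.89, SE 0.13, adjusted p = 0.00256). TFRC (ENSG00000072274), which takes iron-loaded transferrin into the cell, rose 1.46-fold from 53.1 ± 2.40 to 77.3 ± 3.43 CPM (log2 fold change 0.54, SE 0.056, adjusted p = 5.55e-06). IL32 (ENSG00000008517), an inflammatory cytokine, rose 1.22-fold from 64.8 ± 1.74 to 79.1 ± 3.47 CPM (log2 fold change 0.29, SE 0.048, adjusted p = 0.0109). For each of these 4 genes all 5 libraries at 5 µg/ml lay above all 5 controls. Genes with so small a p separate almost by selection, and over all genes tested 333 had libraries entirely above or below control at 5 µg/ml, where chance gives about 127 (0.794% of arrangements).

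The fifth gene that passed at 5 µg/ml was AC020916.1 (ENSG00000267519), a long noncoding RNA without an approved symbol, named here after its values were seen. It fell from 48.6 ± 2.27 to 37.3 ± 3.58 CPM (log2 fold change -0.38, SE 0.071, adjusted p = 0.0464). CXCL6 (ENSG00000124875), a further neutrophil chemokine, was at 2.86 ± 0.35 CPM in control and 4.77 ± 0.64 at 5 µg/ml (log2 fold change 0.74, SE 0.14, adjusted p = 0.0651). LYVE1 (ENSG00000133800), a hyaluronan receptor, had a log2 fold change of -0.43 (SE 0.085, adjusted p = 0.0661), with all 5 libraries at 5 µg/ml below all controls. In all, edgeR called 5 genes at 5 µg/ml, 4 higher and 1 lower, limma-voom 5 and DESeq2 17, and 1343 genes had an unadjusted p below 0.05, more than in any other of 100 splits of these libraries (median 551, highest 1247). edgeR called 12 genes when fitted to only these 2 groups and 137 without a filter on low counts. The count was 3 without control replicate 3, control replicate 5 or replicate 1 at 5 µg/ml, where IL32 had an adjusted p of 0.0504, 0.0714 and 0.0735 (range over its alternatives 1.59e-05 to 0.0735). AC020916.1 passed in only 1 of the 10 models that left out a library, the one without replicate 3 at 5 µg/ml, and its adjusted p ranged up to 0.273 without control replicate 4 (range over its alternatives 3.78e-05 to 0.273).

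**Figure D2:**
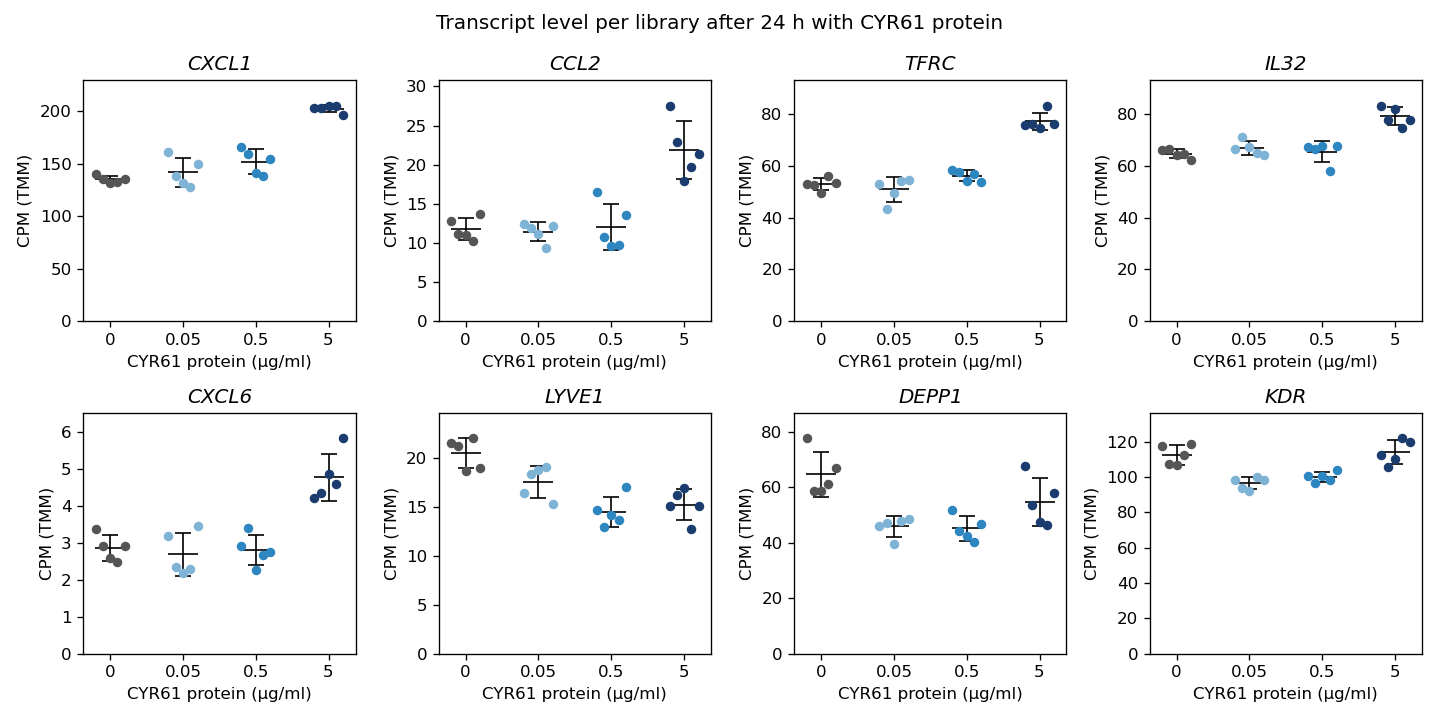
Levels of CXCL1, CCL2, TFRC, IL32, CXCL6, LYVE1, DEPP1 and KDR in CPM (y axis) at 0, 0.05, 0.5 and 5 µg/ml CYR61 (x axis), with 1 point per library, lines at the group means and bars of 1 SD (n = 5 per group). All 5 libraries at 5 µg/ml lie above all 5 controls for CXCL1, CCL2, TFRC, IL32 and CXCL6.

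The list of genes driven by NF-κB in inflammatory activation rose as a group at 5 µg/ml, with a mean log2 fold change of 0.29 and 23 of 26 members above 0 (camera adjusted p = 2.71e-12). It passed with the estimated correlation as well (adjusted p = 0.00382 with an estimated correlation). The mean level of the list was 0.29 log2 units above control (SE 0.086 between libraries), and 4 of the 5 libraries lay above all controls. Over all genes tested, 3 members rose, CXCL1, CCL2 and IL32. When adjusted over the list alone, 9 rose and none fell. Besides CXCL1, CCL2, IL32 and CXCL6, these were CXCL3, ICAM1, CXCL8, CSF3 and TNIP1, the last 5 named after their values were seen. ICAM1, which holds leukocytes to the endothelium, had a log2 fold change of 0.59 (SE 0.16), the chemokine CXCL3 0.77 (SE 0.20), the chemokine CXCL8 0.31 (SE 0.086), the growth factor CSF3 0.35 (SE 0.11) and the NF-κB regulator TNIP1 0.20 (SE 0.071). Their adjusted p values over the list alone ran from 0.0033 for CXCL3 to 0.0258 for TNIP1. At 0.05 and 0.5 µg/ml this list had means of -0.039 and -0.016 and did not pass (adjusted p = 0.914 and 0.553), although the direction of the test was up at both doses, with medians of -0.023 and 0.017.

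Other lists moved less at 5 µg/ml, and their calls were lost with an estimated correlation. Targets of TGF-β and SMAD signalling rose by a mean of 0.11, with 15 of 19 members above 0 (camera adjusted p = 0.0179, and adjusted p = 0.0944 with an estimated correlation). No member passed over all genes tested or adjusted over the list alone. Collagens and other basement membrane genes rose by a mean of 0.063, with 24 of 28 members above 0 (adjusted p = 0.0053, and adjusted p = 0.252 with an estimated correlation), and their mean was 0.024 without control replicate 5 (adjusted p = 0.0443). Among their members, COL8A1 was at 0.22 (SE 0.071), BGN, a proteoglycan, at 0.19 (SE 0.078) and FN1, fibronectin, at 0.11 (SE 0.050). Genes of the G2 and M phases fell to a mean change of -0.052, with 26 of 31 members below 0 and all 5 libraries below all controls in mean level (adjusted p = 0.00197, and adjusted p = 0.228 with an estimated correlation). The mitotic cyclin CCNB1 was at -0.11 (SE 0.040) and the spindle protein NUSAP1 at -0.095 (SE 0.041), and neither passed.

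Nuclear genes of oxidative phosphorylation fell to a mean change of -0.038 at 5 µg/ml, with 28 of 36 members below 0 (camera adjusted p = 0.0053, and adjusted p = 0.63 with an estimated correlation). Ribosomal protein genes fell to a mean change of -0.026, with 43 of 60 below 0 (adjusted p = 0.00698, and adjusted p = 0.664 with an estimated correlation), while their share of counts was 7.56% against 7.68% in control. Without replicate 4 at 5 µg/ml, 3 lists passed in place of 6, with adjusted p = 0.0693 for the TGF-β list, 0.121 for oxidative phosphorylation and 0.24 for ribosomal proteins. Without replicate 5 at 5 µg/ml the adjusted p was 0.122 for oxidative phosphorylation and 0.562 for ribosomal proteins, whose mean turned to 0.00047, and without control replicate 3 that for ribosomal proteins was 0.0866. The oxidative phosphorylation mean was -0.068 without replicate 1, -0.021 without replicate 4 and -0.019 without replicate 5 at 5 µg/ml. The ribosomal mean was -0.051 without replicate 1, -0.0084 without replicate 4 at 5 µg/ml and -0.039 without control replicate 4.

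At 0.5 µg/ml, genes that mark and join endothelial cells fell as groups while no single gene passed in edgeR. With an estimated correlation the junction genes passed (adjusted p = 0.00769) and the identity genes that mark endothelium did not (adjusted p = 0.132). Among genes with an approved symbol the smallest p values belonged to LYVE1, DEPP1 and PECAM1, each with all 5 libraries at 0.5 µg/ml below all controls. LYVE1 was at 20.5 ± 1.54 CPM in control and 14.5 ± 1.55 at 0.5 µg/ml (log2 fold change -0.50, SE 0.084, edgeR adjusted p = 0.0574). DEPP1 (ENSG00000165507), a target of FOXO transcription factors, was at 64.5 ± 8.05 and 45.1 ± 4.44 CPM (log2 fold change -0.52, SE 0.094, adjusted p = 0.0798). PECAM1 (ENSG00000261371), an adhesion molecule of endothelial junctions, was at 1134 ± 36.1 and 1009 ± 25.3 CPM (log2 fold change -0.17, SE 0.034, adjusted p = 0.162). DESeq2 called 17 genes and limma-voom 1, and 959 genes had an unadjusted p below 0.05 in edgeR, a number that 17 of 100 splits of these libraries reached, the real one included (median of the others 600). Without replicate 5 at 0.5 µg/ml, edgeR called LYVE1 (adjusted p = 0.0116, range over its alternatives 1.08e-05 to 0.321). It called 132 genes without a filter on low counts, and 1, DEPP1, with the replicate number as a block.

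The list of junction and permeability genes fell to a mean change of -0.11 at 0.5 µg/ml, with 17 of 20 members below 0 (camera adjusted p = 0.000155, and adjusted p = 0.00769 with an estimated correlation). Adjusted over the list alone, PECAM1 and GJA1 fell, and over all genes tested none did. GJA1, which encodes the gap junction protein connexin 43, had a log2 fold change of -0.17 (SE 0.046). The list of angiogenesis and tip cell genes fell to a mean change of -0.085, with 17 of 23 members below 0 (adjusted p = 0.00259, and adjusted p = 0.039 with an estimated correlation). Of its members 5 fell and 1 rose adjusted over the list alone, and over all genes tested none did. Among those that fell were the VEGF receptor gene KDR (log2 fold change -0.17, SE 0.045) and, chosen after their values were seen, ANGPT2, the ligand of the TIE2 receptor (-0.22, SE 0.054), the chemokine receptor CXCR4 (-0.37, SE 0.12) and the peroxidase PXDN (-0.14, SE 0.038). The list of endothelial identity genes fell to a mean change of -0.099, with 19 of 28 members below 0 (adjusted p = 0.000155, and adjusted p = 0.132 with an estimated correlation), and adjusted over the list alone LYVE1 and PECAM1 fell. Fatty acid synthesis genes fell to a mean change of -0.092, with 11 of 14 below 0 (adjusted p = 0.0162, and adjusted p = 0.132 with an estimated correlation). Among them ACLY, which makes cytosolic acetyl-CoA and was chosen after its values were seen, fell adjusted over the list alone (-0.16, SE 0.043).

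Lists for protein synthesis and mitochondria rose slightly at 0.5 µg/ml. Ribosomal protein genes rose by a mean of 0.040, with 58 of 60 members above 0 (camera adjusted p = 2.16e-06, and adjusted p = 0.522 with an estimated correlation), and their share of counts was 7.86% against 7.68% in control. Nuclear genes of oxidative phosphorylation rose by 0.046, with 32 of 36 above 0 (adjusted p = 0.00104, and adjusted p = 0.522 with an estimated correlation). Genes encoded in the mitochondrial genome rose by 0.045, with 10 of 13 above 0 (adjusted p = 0.0495, and adjusted p = 0.522 with an estimated correlation). Targets of ATF4, a factor of the amino acid response, rose by 0.058, with 18 of 22 above 0 (adjusted p = 0.0239, and adjusted p = 0.483 with an estimated correlation). The ATF4 call was lost without control replicate 1 (adjusted p = 0.081) or 5 (0.201), or replicate 2 (0.133) or 3 (0.0648) at 0.5 µg/ml, with a mean of 0.029 without control replicate 5, and the fatty acid call without control replicate 2 (0.0592). The mitochondrial genome call was kept only without control replicate 3, control replicate 5 or replicate 4 at 0.5 µg/ml, and its adjusted p reached 0.178 without replicate 3 at 0.5 µg/ml.

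At 0.05 µg/ml, the lowest dose, angiogenesis and junction genes again fell as groups, and metallothionein, ribosomal protein and mitochondrial genes rose as groups, while no single gene passed in edgeR. The rises were lost with an estimated correlation (adjusted p = 0.107 for metallothioneins, 0.156 for ribosomal proteins, 0.298 for oxidative phosphorylation and 0.192 for the mitochondrial genome), and the falls were not (0.0315 for both). The 3 smallest p values among genes with an approved symbol and a mean of at least 1 CPM belonged to DEPP1, SLC39A10 and BCYRN1. These and KDR (ENSG00000128052), which passed the joint test over the doses, had all 5 libraries at 0.05 µg/ml on 1 side of all controls. KDR was at 113 ± 5.60 CPM in control and 96.5 ± 3.29 at 0.05 µg/ml (log2 fold change -0.22, SE 0.046, edgeR adjusted p = 0.173). DEPP1 was at 64.5 ± 8.05 and 45.8 ± 3.67 CPM (log2 fold change -0.49, SE 0.094), and the zinc transporter gene SLC39A10 (ENSG00000196950) at 56.6 ± 2.83 and 46.5 ± 4.50 CPM (log2 fold change -0.28, SE 0.055). BCYRN1 (ENSG00000236824), a noncoding RNA, was at 21.4 ± 2.37 and 29.2 ± 3.71 CPM (log2 fold change 0.45, SE 0.091), and the adjusted p was 0.173 for these 3 genes as well. DESeq2 called 35 genes and limma-voom 0, and 1618 genes had an unadjusted p below 0.05 in edgeR, 749 higher and 869 lower, a number that 16 of 100 splits of these libraries reached, the real one included (median of the others 958). Without replicates 1, 2 and 3 at 0.05 µg/ml, which stood apart, edgeR called 2 genes. It called 178 without a filter on low counts, and 1, DEPP1, with the replicate number as a block.

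The angiogenesis list fell to a mean change of -0.12 at 0.05 µg/ml, with 14 of 23 members below 0 (camera adjusted p = 0.00219, and adjusted p = 0.0315 with an estimated correlation). Adjusted over the list alone KDR, ANGPT2 (log2 fold change -0.23, SE 0.054) and CXCR4 (-0.42, SE 0.13) fell, the last 2 chosen after their values were seen, and over all genes tested none did. The junction list fell to a mean change of -0.074, with 16 of 20 members below 0 (adjusted p = 0.00304, and adjusted p = 0.0315 with an estimated correlation). With the trend with gene length and GC content removed, its mean was nearer to control and it did not pass with an estimated correlation. Adjusted over the list alone GJA1 (-0.17, SE 0.046), TJP1 and CTNND1, which anchor tight and adherens junctions and were chosen after their values were seen (-0.17, SE 0.051 and -0.17, SE 0.053), and PECAM1 (-0.10, SE 0.034) fell. Targets of NRF2, which answers oxidative stress, rose by a mean of 0.050, with 18 of 23 above 0 (adjusted p = 0.00666, and adjusted p = 0.0315 with an estimated correlation). Its member NQO1, a quinone reductase, rose adjusted over the list alone at all 3 doses, by 0.15 (SE 0.035), 0.14 (SE 0.035) and 0.15 (SE 0.035). The 3 comparisons share their control libraries, so these are not 3 separate observations. Without the 3 libraries at 0.05 µg/ml that stood apart, none of these lists passed (adjusted p = 0.162 for angiogenesis, 0.22 for junctions and 0.0953 for NRF2), and without replicate 2 alone the junction mean was -0.047 (adjusted p = 0.0095).

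Ribosomal protein genes rose by a mean of 0.10 at 0.05 µg/ml, with 59 of 60 members above 0 (camera adjusted p = 1.07e-28, and adjusted p = 0.156 with an estimated correlation). Of these, 17 rose adjusted over the list alone and none over all genes tested, among them RPS27 (log2 fold change 0.16, SE 0.043) and RPL38 (0.12, SE 0.045), both chosen after their values were seen. Nuclear genes of oxidative phosphorylation rose by 0.091, with 36 of 36 above 0 (adjusted p = 1.4e-11, and adjusted p = 0.298 with an estimated correlation), and genes of the mitochondrial genome by 0.093, with 11 of 13 above 0 (adjusted p = 6.37e-06, and adjusted p = 0.192 with an estimated correlation). The ribosomal share of counts was 8.10% against 7.68% in control. Without the 3 libraries that stood apart, the means were 0.063 for ribosomal proteins (adjusted p = 0.000112, and adjusted p = 0.681 with an estimated correlation), 0.026 for oxidative phosphorylation (adjusted p = 0.559) and 0.018 for the mitochondrial genome (adjusted p = 0.676).

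Metallothioneins, which bind zinc and copper, rose by a mean of 0.19 at 0.05 µg/ml, with 6 of 7 above 0 (camera adjusted p = 0.000308, and adjusted p = 0.107 with an estimated correlation). Of them MT2A (log2 fold change 0.28, SE 0.070), MT1X (0.28, SE 0.067) and MT1E (0.29, SE 0.066) rose adjusted over the list alone. Heat shock genes rose by a mean of 0.044, with 12 of 15 above 0 (adjusted p = 0.0154, and adjusted p = 0.13 with an estimated correlation), and ATF4 targets by 0.065, with 17 of 22 above 0 (adjusted p = 0.0294, and adjusted p = 0.48 with an estimated correlation). Endothelial identity genes fell to a mean change of -0.056, with 18 of 28 below 0 (adjusted p = 0.0443, and adjusted p = 0.437 with an estimated correlation). Adjusted over the list alone PECAM1, the angiopoietin receptor gene TEK (-0.18, SE 0.055) and MMRN1 (-0.22, SE 0.062) fell, the last 2 chosen after their values were seen. The identity call was lost without control replicate 1 (adjusted p = 0.3) or 3 (0.0541), or replicate 1 (0.514) or 3 (0.199) at 0.05 µg/ml, and the ATF4 call without control replicate 1 (0.102) or 5 (0.226), or replicate 2 (0.0673) or 4 (0.48) at 0.05 µg/ml. The identity mean ran from -0.022 without replicate 1 to -0.096 without replicate 4 at 0.05 µg/ml, was -0.027 without control replicate 1 and was -0.032 without replicate 3. The ATF4 mean ran from 0.019 without replicate 4 to 0.11 without replicate 1 at 0.05 µg/ml and was 0.036 without control replicate 5. Without the 3 libraries that stood apart, metallothioneins (adjusted p = 0.0997), heat shock genes (0.583) and identity genes (0.676, with a mean turned to 0.032) did not pass, and ATF4 targets did (0.00325, and adjusted p = 0.39 with an estimated correlation).

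In all, 15 of the 35 tested lists passed camera at 1 dose or more, in 24 pairs of list and dose. In each of those pairs the mean, the median and the test had the same direction, and none turned with other scaling factors. When the libraries were split in other ways (100 splits with the real one included), camera still called lists in 85, 56 and 78 of the other splits at 0.05, 0.5 and 5 µg/ml. The medians were 3, 1 and 2 lists. Each of these splits keeps more libraries of 1 real group on each side, so its calls can hold part of the real difference. How many lists camera calls without any difference was therefore not measured, and passing it does not by itself set the real groups apart. With an estimated correlation 3 lists passed at 0.05, 2 at 0.5 and 1 at 5 µg/ml. The other 20 lists did not pass camera with the preset correlation at any dose, with a smallest adjusted p of 0.0516 for contractile genes of the endothelial to mesenchymal transition at 5 µg/ml. With fry, 1 of these 20, genes of flow and quiescence, passed at 0.5 µg/ml (adjusted p = 0.0292, range over its alternatives 0.0292 to 0.195, and 0.0649 with camera). Markers of other cell types were among the 20, with 5 tested genes for leukocytes, 5 for epithelium and 7 for smooth muscle and fibroblasts, and none of the 12 markers of red cells and platelets was expressed highly enough to test. Of 8 markers of lymphatic endothelium 3 were tested, too few for a list test, and all 3 were below 0 at each dose. Adjusted over that list alone LYVE1, which is also in the endothelial identity list, fell at all 3 doses, and FLT4, a VEGF receptor gene, fell at 0.05 µg/ml. Changes shared by the doses are not separate observations, because the control libraries are the same.

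The doses were then compared with each other. Between 5 and 0.5 µg/ml, the inflammatory genes and TFRC were also higher at the higher dose. All comparisons with 5 µg/ml use the same 5 libraries of that dose and share the chance values of those libraries. TFRC rose 1.37-fold (log2 fold change 0.46, SE 0.056, edgeR adjusted p = 0.000281), CXCL1 1.33-fold (0.42, SE 0.056, adjusted p = 0.000778), CCL2 1.82-fold (0.86, SE 0.13, adjusted p = 0.00377), IL32 1.21-fold (0.28, SE 0.048, adjusted p = 0.0215) and CXCL6 1.70-fold (0.77, SE 0.14, adjusted p = 0.0405). MORC4 (ENSG00000133131), a chromatin ATPase gene, fell from 7.42 ± 0.54 to 5.45 ± 0.29 CPM (-0.45, SE 0.083, adjusted p = 0.0405). These 6 were all genes edgeR called, limma-voom called 5 and DESeq2 16, and 1511 genes had an unadjusted p below 0.05. Fitted to only these 2 groups, edgeR called 202 genes, 168 higher and 34 lower, and it called 301 without a filter on low counts. The count was 3 without replicate 4 at 0.5 µg/ml and without replicate 1, 2, 3 or 5 at 5 µg/ml, where IL32 had an adjusted p of 0.109, 0.112, 0.058, 0.121 and 0.0501 (range over its alternatives 8.57e-05 to 0.121). MORC4 did not pass in any of the 10 models that left out a library (adjusted p up to 0.2 without replicate 3 at 0.5 µg/ml), and CXCL6 passed only without replicate 2 at 0.5 µg/ml (up to 0.227 without replicate 5 at 5 µg/ml).

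Tested directly between 0.5 and 5 µg/ml, the NF-κB list was lower at 0.5 µg/ml with a mean difference of -0.30 (camera adjusted p = 3.33e-10, and adjusted p = 0.00568 with an estimated correlation). The junction list was lower at 0.5 µg/ml with -0.17 (adjusted p = 0.000152, and adjusted p = 0.00568 with an estimated correlation), the angiogenesis list with -0.095 (adjusted p = 0.000622, and adjusted p = 0.015 with an estimated correlation) and the endothelial identity list with -0.14 (adjusted p = 3.24e-06, and adjusted p = 0.0391 with an estimated correlation). Between 0.05 and 5 µg/ml the NF-κB list was lower at 0.05 µg/ml with -0.33 (adjusted p = 3.62e-09, and adjusted p = 0.0198 with an estimated correlation), the junction list with -0.13 (adjusted p = 0.00336, and adjusted p = 0.0233 with an estimated correlation) and the angiogenesis list with -0.13 (adjusted p = 0.000721, and adjusted p = 0.0215 with an estimated correlation). In all, 10 lists passed camera between 0.5 and 5 µg/ml and 11 between 0.05 and 5 µg/ml, and with an estimated correlation only the 4 and 3 named here did. The endothelial identity list between 0.05 and 5 µg/ml was among those lost (adjusted p = 0.00677, and adjusted p = 0.19 with an estimated correlation). Against control at 5 µg/ml the junction, angiogenesis and identity lists did not pass. The mean there was 0.010 for angiogenesis (camera adjusted p = 0.611) and 0.041 for identity (0.381), and the -log10 of the camera p was 0.133 for junctions. The junction mean at 5 µg/ml lay above control, since the list at 0.5 µg/ml was further below 5 µg/ml (-0.17) than below control (-0.11). Between 0.5 and 0.05 µg/ml 5 lists passed camera and 0 with an estimated correlation. Ribosomal protein genes (mean difference -0.062, adjusted p = 2.24e-16), nuclear genes of oxidative phosphorylation (-0.046, adjusted p = 2.68e-05), genes of the mitochondrial genome (-0.048, adjusted p = 0.00356) and metallothioneins (-0.16, adjusted p = 0.00356) were lower at 0.5 µg/ml, and targets of YAP and TAZ higher (0.13, adjusted p = 0.00356). Their adjusted p values with an estimated correlation ran from 0.398 to 0.726.

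Between 0.5 and 0.05 µg/ml no gene passed in edgeR (639 genes with an unadjusted p below 0.05), limma-voom called 0 and DESeq2 3. Among genes with an approved symbol and a mean of at least 1 CPM, the smallest p there belonged to LBX2-AS1, SRCAP and BST2. LBX2-AS1 (ENSG00000257702), an antisense RNA whose reads cannot be told from those of the opposite strand, had a log2 fold change of -0.73 (SE 0.13, adjusted p = 0.0507). SRCAP (ENSG00000080603), a chromatin remodelling gene, was at -0.76 (SE 0.17, adjusted p = 0.667), and BST2 (ENSG00000130303), an antiviral protein gene, at -0.26 (SE 0.061, adjusted p = 0.85). Without replicate 3 at 0.05 µg/ml edgeR called 1 gene.

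A joint test over the 3 doses called 9 genes. CXCL1 (edgeR adjusted p = 2.63e-06), TFRC (2.03e-06), CCL2 (0.000494), IL32 (0.0127) and CXCL6 (0.0163) had their highest mean at 5 µg/ml. LYVE1 (adjusted p = 0.0279), DEPP1 (0.0316) and KDR (0.0316) had lower means than control at the lower doses, and at 5 µg/ml LYVE1 was at 15.2 ± 1.56, DEPP1 at 54.5 ± 8.68 and KDR at 114 ± 6.80 CPM. BCYRN1 (adjusted p = 0.00171) was at 21.4 ± 2.37 CPM in control, 29.2 ± 3.71 at 0.05, 24.4 ± 2.50 at 0.5 and 17.8 ± 1.55 at 5 µg/ml. A linear trend with the order of the doses was called for CXCL1 (log2 slope 0.19 per dose step, SE 0.023, adjusted p = 0.000202) and TFRC (0.18, SE 0.027, adjusted p = 0.00475). The steps were not even. In the order control, 0.05, 0.5 and 5 µg/ml, mean levels were 135, 142, 152 and 203 CPM for CXCL1. For TFRC they were 53.1, 51.0, 56.3 and 77.3 CPM, so TFRC did not rise at 0.05 µg/ml. For the joint test DESeq2 called 152 genes and limma-voom 11, and edgeR 14 without replicate 1 and 15 without replicate 4 at 0.05 µg/ml and 4 without replicate 5 at 5 µg/ml. For the trend DESeq2 called 10 genes and limma-voom 2, and edgeR 6 without replicate 4 at 0.5 µg/ml.

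Across the 16026 genes, which are not independent replicates, the log2 fold changes against control correlated with r = 0.523 between 0.05 and 0.5 µg/ml, 0.454 between 0.05 and 5 µg/ml and 0.497 between 0.5 and 5 µg/ml. Unchanged groups simulated against shared controls gave mean r of 0.496, 0.495 and 0.5. The covariances were 0.0363, 0.0345 and 0.0354 against 0.0293, 0.0294 and 0.0293 in the simulations, differences of 0.00703, 0.00509 and 0.00607. With the controls split so that no control library was used in both comparisons, the median r was 0.0643, 0.0482 and 0.0675 over 20 values each. At an unadjusted p below 0.05, 148 genes were higher and 258 lower at both 0.05 and 0.5 µg/ml, where unchanged groups with shared controls gave a mean of 86.4 (63 to 108 over 100 simulations) and 73.3 (54 to 100), and independent lists would share 20.0 and 28.9. For 0.05 and 5 µg/ml these were 101 higher and 134 lower, against 87.1 (69 to 117) and 71.9 (50 to 98) in the simulations and 31.3 and 36.5 for independent lists. For 0.5 and 5 µg/ml they were 121 and 111, against 88.4 (62 to 107) and 72.7 (48 to 97) in the simulations and 17.9 and 22.3 for independent lists. Because the simulations drew genes independently of each other, their ranges are likely narrower than correlated genes would give. Overlaps above those ranges therefore do not exclude chance.

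The authors' deposited tables list 13329 genes for each dose. In the authors' deposited table for 5 µg/ml 9 genes passed an adjusted p of 0.05, 5 higher (CXCL1, TFRC, CCL2, IL32 and CXCL6) and 4 lower (AC020916.1, FCF1, LYVE1 and LINC02603, of which FCF1 and LINC02603 are named after their values were seen), and the 5 genes called by edgeR were among them. In the authors' deposited table for 0.5 µg/ml LYVE1 (adjusted p = 0.0347) and DEPP1 (adjusted p = 0.0436) passed, both lower, and in the authors' deposited table for 0.05 µg/ml no gene passed, with 1098 at an unadjusted p below 0.05. Across the genes in both, the fold changes of the authors' deposited tables correlated with those of edgeR with r = 0.919, 0.897 and 0.901 at 0.05, 0.5 and 5 µg/ml.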

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

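A rule fixed beforehand picked out a library whose distance from the nearest of the other 4 libraries of its group was more than 0.71 of the range of the group. Of 88 groups of 5 values, 3 were picked out, and chance flags about 1 in 20 groups. CXCL1 was at 197 CPM in replicate 5 at 5 µg/ml, below the 203 to 205 CPM of the other libraries of that group. TFRC was at 83.3 CPM in replicate 4 at 5 µg/ml, above the 74.7 to 76.4 CPM of the others. IL32 was at 58.2 CPM in replicate 4 at 0.5 µg/ml, below the 66.5 to 67.6 CPM of the others. No explanation was tested for these values.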

How the results depend on the processing

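Alternatives chosen after the data were examined were the removal of the length and GC trend and the removal of 3 libraries at 0.05 µg/ml. Counts of changed genes are given in the order 0.05, 0.5 and 5 µg/ml against control, 5 against 0.5, 0.5 against 0.05, any dose and trend, where edgeR called 0, 0, 5, 6, 0, 9 and 2. Without a filter on low counts they were 178, 132, 137, 301, 54, 687 and 7, of which 25, 19, 20, 30, 14, 111 and 1 came from genes the filter removes. DESeq2 gave 35, 17, 17, 16, 3, 152 and 10, and limma-voom 0, 1, 5, 5, 0, 11 and 2. Models of only the libraries compared gave 12 at 5 µg/ml and 202 for 5 against 0.5. An adjusted p below 0.01 left 3 at 5 µg/ml, 3 for 5 against 0.5 and 4 for any dose, and an absolute log2 fold change of at least 0.5 left 3 and 2 for the first pair. DESeq2 size factors and the upper quartile each gave 2 for 0.5 against 0.05. With the length and GC trend removed, limma-voom gave 2 at 0.5 µg/ml, 2 for 0.5 against 0.05 and 5 for the dose trend, against 1, 0 and 2 in limma-voom without the removal. It gave 5 at 5 µg/ml, 6 for 5 against 0.5 and 9 for any dose, of which 4, 5 and 6 were also called by edgeR. Lists that passed after this removal numbered 8, 6 and 5 at 0.05, 0.5 and 5 µg/ml. Without the 3 libraries, 2 passed at 0.05 and 13 at 5 µg/ml, and 3 lists at 0.05 µg/ml. Lists that passed at 0.05, 0.5 and 5 µg/ml numbered 10, 8 and 6, against 3, 2 and 1 with an estimated correlation and 5, 4 and 3 with fry. With each library left out in turn, genes ran from 0 to 0, 0 to 1, 3 to 5, 3 to 5, 0 to 1, 4 to 15 and 2 to 6, and lists from 8 to 11, 6 to 9 and 3 to 8. The log2 fold change of CCN1 ran from 0.0030 to 0.084, 0.042 to 0.11 and 0.082 to 0.15 in these models, and library properties passed in 0 to 0 tests. The correlations of fold changes between doses fell to 0.0643, 0.0482 and 0.0675 with split controls, which removes the shared libraries by construction, and were 0.611 and 0.48 with the stricter filter for 0.05 with 0.5 and 0.05 with 5 µg/ml. For the other differences the cause was not tested. With the replicate number as a block, genes numbered 1, 1, 4, 6, 0, 15 and 2, and lists 10, 8 and 7. DEPP1 then passed at 0.05 µg/ml (adjusted p = 0.0048, range over its alternatives 2.35e-10 to 0.519) and 0.5 µg/ml (0.00184, range 1.36e-11 to 0.371), while AC020916.1 at 5 µg/ml (adjusted p = 0.145, range 3.78e-05 to 0.273) and MORC4 at 5 against 0.5 µg/ml (0.0985, range 0.0139 to 0.2) did not. Over all genes the numbers showed no pairing of the samples. Same-numbered libraries of different groups correlated from -0.096 to 0.099, and 3 of 20 libraries matched their own number best. A correlation over all genes cannot exclude an effect shared by same-numbered libraries in single genes, so the calls gained with the block stay open. Of the alternatives for 70 fold changes of named genes, 1166 kept their direction and side of the threshold, 39 lost the threshold and 55 gained it. For 24 list means these were 276 kept and 60 lost, and none of either kind reversed past the threshold. At this depth and with 5 libraries per group, 74% of genes changed 1.5-fold at 5 µg/ml were recovered in simulated counts, and most smaller differences were not detectable gene by gene. The simulated counts held 200 changed genes, which eases the adjusted threshold, so the share may be lower in these data, where few genes passed.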

Other observations

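The tests of leukocyte markers and of oxidative phosphorylation without 3 libraries, the removal of the length and GC trend, the removal of those 3 libraries and the tests of lists between doses were chosen after the results were seen. PTX3, a pattern recognition protein of the NF-κB list, rose adjusted over the list alone at 0.05 µg/ml (log2 fold change 0.19, SE 0.054) and 0.5 µg/ml (0.23, SE 0.054), the doses at which that list did not pass. THBS1, an inhibitor of angiogenesis in the list of TGF-β targets, fell at 0.05 µg/ml adjusted over the list alone (-0.18, SE 0.050). Neither passed over all genes tested, and PTX3 was chosen after its values were seen.

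The list of CYR61 receptors, integrins and heparan sulfate proteoglycans had a mean level 0.15 log2 units above control at 5 µg/ml (SE 0.050 between libraries), with all 5 libraries above all controls, and did not pass camera (adjusted p = 0.1). Its member ITGAV, the integrin chain αv, rose at 5 µg/ml adjusted over the list alone (log2 fold change 0.23, SE 0.069, list-adjusted p = 0.0393). Interferon-stimulated genes had 23 of 31 members above 0 at 5 µg/ml and did not pass (adjusted p = 0.0868), with MX1 at 0.93 (SE 0.36) and ISG15 at 0.13 (SE 0.065), neither of which passed. Without replicate 2 at 5 µg/ml MX1 was at 0.31, and without replicate 1 ISG15 was at 0.084. The 1 member that passed adjusted over the list alone went the other way, since BST2 fell (-0.26, SE 0.061). Compared directly, the interferon list was lower at 0.5 than at 5 µg/ml with a mean difference of -0.24 (adjusted p = 0.000574, and adjusted p = 0.0912 with an estimated correlation). The basement membrane list was lower at 0.5 than at 5 µg/ml with -0.13 (adjusted p = 5.93e-06, and adjusted p = 0.091 with an estimated correlation).

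The rise of the NF-κB list at 5 µg/ml was weighed against technical explanations. With the trend with gene length and GC content removed, its mean was 0.2735 against 0.29 before (adjusted p = 4.46e-13, SE 0.080 between libraries), which argues against that trend as the whole cause. Leukocytes in the cultures would bring their own transcripts. Of 17 leukocyte markers counted in any library, only the 14 below 1 CPM in control were summed. They rose together by 0.131 CPM, from 1.22 to 1.35 CPM, while CXCL1 and CCL2 rose together by 77.3 CPM. These sums bear only on leukocytes as the direct source of the CXCL1 and CCL2 transcripts. Another substance in the protein preparation cannot be told apart from CYR61, because the labels describe 0 groups given buffer or an inactive preparation. The hypothesis that 5 µg/ml CYR61 itself raises NF-κB targets may hold, but stays untested against that alternative.

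The rise of ribosomal protein and oxidative phosphorylation genes at 0.05 µg/ml was weighed in the same way. With the length and GC trend removed, the ribosomal mean was 0.1078 against 0.10 before (SE 0.037 between libraries, adjusted p = 2.2e-24, and adjusted p = 0.25 with an estimated correlation against 0.156 before), which argues against that trend as the whole cause of a call that the estimated correlation does not keep. Without the 3 libraries that stood apart, the oxidative phosphorylation mean was 0.02638 against 0.091 (SE 0.042, adjusted p = 0.559), as those libraries being a candidate source would predict. With 2 libraries left a call is also lost through lower power, so an effect of the dose is not excluded for this list. The ribosomal mean was then 0.06339 (SE 0.044, adjusted p = 0.000112, and adjusted p = 0.681 with an estimated correlation), and with 2 libraries left whether it comes from those libraries cannot be told apart from an effect of the dose. A different state of those 3 cultures or of their RNA stays open as well.

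The lower junction genes at 0.05 and 0.5 µg/ml were weighed against length and GC content and against the shared controls. With the trend removed, the mean at 0.5 µg/ml was -0.1142 against -0.11 before (adjusted p = 0.000338, SE 0.029 between libraries), which argues against that trend at this dose. Chance values of the control libraries would not move the junction list between treated groups, but it was lower at 0.5 than at 5 µg/ml, where no control enters (limma camera adjusted p = 0.000152, and 2.6e-05 before adjustment). At 5 µg/ml the junction list showed no clear difference from control (-log10 of the camera p 0.133), so its level did not fall steadily with dose. Its mean at 5 µg/ml lay above control, which makes up part of the difference between 0.5 and 5 µg/ml (-0.17). The comparison with 5 µg/ml therefore does not settle whether the fall against control holds chance values of the controls. That junction transcripts are lower at 0.5 µg/ml than at 5 µg/ml because of the dose stays a hypothesis. Groups given buffer or an inactive protein, in separate cultures, would be needed to test it. At 0.05 µg/ml the mean was -0.044 with the trend removed against -0.074 before (adjusted p = 0.0147, and adjusted p = 0.115 with an estimated correlation), and the call was lost without the 3 libraries that stood apart (adjusted p = 0.22), which leaves the trend and those libraries open there.

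Other splits of the libraries compared were refitted, 100 for each result with the real one included. At 5 µg/ml the real split called 5 genes and the highest other 0. For 5 against 0.5 µg/ml these were 6 and 0, for any dose 9 and 1, and for the trend 2 and 0. In each of these 1 of 100 splits gave as many, the real one, which argues against a chance arrangement of these libraries. No share below 1 of 100 could be reached. Chance between cultures was not tested, since the libraries of a group may not be separate cultures. For the NF-κB list at 5 µg/ml the -log10 of the camera p was 13.1 in the real split and 10.9 in the highest other, again 1 of 100, with the same limits. The median of the other splits was 1.40. With 5 libraries per group, each other split of 2 groups still holds more libraries of 1 real group on each side. A small camera p there can therefore hold part of the real difference and does not measure chance alone. Lists passing at 0.05 µg/ml numbered 10 in the real split and 10 in the highest other (2 of 100 as many), and at 0.5 µg/ml 8 and 8 (3 of 100). These shares lie under 0.05. Other splits still reached the same counts, and lists were called in 85 and 56 of them. Those splits keep part of the real difference, so their calls are not all due to chance by design. Chance is still not excluded for these counts of camera calls. At 5 µg/ml 6 lists passed and 9 in the highest other (7 of 100), so chance cannot be excluded for that count. For the counts of 0 genes at 0.05 and 0.5 µg/ml and between them, 100 of 100 splits gave at least as many, as any split must, so these splits say nothing about chance there, and the highest others were 1143, 7 and 241. The 1143 genes came from the split that put control replicates 1, 2 and 3 with replicates 4 and 5 at 0.05 µg/ml, and the 241 from the one that put replicates 1, 2 and 3 at 0.05 with replicates 2 and 3 at 0.5 µg/ml. Splits that call many genes where the real one calls none point to a structure of the samples other than the dose. In both, replicates 1, 2 and 3 at 0.05 µg/ml lie on 1 side, together with control replicates 4 and 5 in the first and with replicates 2 and 3 at 0.5 µg/ml in the second.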
